A study of Mus musculus with 6 samples.

How the data were processed

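The data were 6 scanner files, 1 per array, and a table of processed values, all from cells labelled as primary Sertoli cells of C57BL/6J mice. Per the labels' protocols, the isolated cells were kept at 34 °C in F12/DMEM with 10 µg/ml insulin, 5 µg/ml transferrin and 5 ng/ml EGF. The medium was changed on days 2 and 4, and vehicle, bFGF (20 ng, volume not stated) or 10 µM PD0325901 was given from day 5 for 24 h. Labelled RNA was made from 0.4 µg of total RNA with a 1-colour Cy3 kit, per the labels' protocols. Groups and replicate numbers were taken from the labels, and each group held 2 arrays.

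The scanner files hold spot intensity on a linear scale, which Agilent Feature Extraction 9.5.3.1 wrote, per the file headers (version 9.5 per the submitters' processing notes). The processed intensity that the authors deposited is background-subtracted and detrended within the array, per the file headers, and is not normalized between arrays. The table of log2 values that the authors deposited was set against the scanner files: for 100% of unflagged probes it equals the log2 processed signal scaled per array and centred on the probe's median over the 6 arrays, within 0.001. Its direction is that of the scanner signal. The constants that scale its arrays, relative to one another, lay within 0.0084 of those of the 75th percentile on the log2 scale, and only a constant common to all arrays stays unknown. The medians of its columns were 0.020 and 0.018 for vehicle, 0.0050 and 0.0042 for bFGF and -0.107 and -0.012 for PD0325901. It served as an alternative.

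From the scanner files, the log2 processed signal minus each array's 75th percentile was computed for 43379 non-control spots. Spots of 1 probe were averaged on the log2 scale, and control spots and spots with an outlier flag were left out, which removed 83 probes that were flagged on every spot of an array. No spot was saturated. Of 41174 probes, 23374 (56.8%) were named through the RefSeq accession in the files and a RefSeq gene table of assembly GRCm38.p6. This gave 16535 genes, and 17800 probes had no gene name and entered only an added alternative. The array files were built on an older assembly, so no coordinates are given. A probe was detected where it was well above background on both arrays of at least 1 group, and the detected probe with the highest mean stood for its gene. The lowest signal well above background was 11.0 and 11.4 on the bFGF arrays, 19.8 and 22.1 on the vehicle arrays and 15.2 and 19.3 on the PD0325901 arrays.

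Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in 1 model over all 6 arrays with 3 residual degrees of freedom, with Benjamini-Hochberg adjustment over 14236 genes and a threshold of 0.05. Where a gene was not well above background on any array of a group, a lower bound of the fold is given: the mean of the bright group against the mean of, per array, the higher of the lowest signal well above background and the gene's own signal. That lowest signal is not a strict limit of detection. On the PD0325901 arrays it was -6.63 and -6.26 on the log2 scale. Has2 lay above it there (-6.12 and -6.14) but was well above background on only 1 array. A higher floor would give smaller bounds. The model was tested on simulated data of 14236 genes for the comparison of PD0325901 with vehicle, where it recovered 0% of genes changed 1.2-fold, 46% at 1.5-fold, 66% at 2-fold and 90% at 4-fold, 50 of each, and called 5 unchanged genes. So few changed genes make the adjustment stricter than in the comparison itself, where 7596 genes passed. The shares recovered therefore do not carry over to it, and smaller changes passed there. The 2 arrays of a group differed by more than spot noise: over 174 probes with 10 spots each, the median ratio of the variance between arrays to that expected from the spots was 3.31 for vehicle, 2.52 for bFGF and 2.71 for PD0325901, against 0.474 by chance. Separate hybridisations of 1 RNA could differ as much, and each array counted as 1 sample as in the labels.

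Before the data files were seen, 22 gene lists were fixed. They were 15 lists of function (ERK pathway output and feedback, spermatogonial niche factors, Sertoli cell identity and function, retinoid metabolism and signalling, cell cycle, cell junctions, matrix proteases and inhibitors, extracellular matrix, cholesterol synthesis, glycolysis and lactate, interferon response, cytokines and acute inflammation, stress response and apoptosis, growth factor receptors, and FSH and cAMP signalling) and 7 lists of markers of other cells (peritubular myoid, Leydig, macrophage, germ, endothelial, fibroblast, and rete and epithelial cells). Each was tested with camera, which compares a list with all other genes, with a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera tests on the 3 residual degrees of freedom, so even a clear shift may not pass. A list that did not pass in that form is therefore not shown to be unshifted. Some genes stand in more than 1 list. The rule for the genes named, also fixed then, takes several sets. They are, in each comparison the 10 largest rises and the 10 largest falls by log2 signal, above background or not, among genes that passed, whose arrays did not overlap between the groups and whose symbol was not a clone name, 12 genes in every comparison (Gdnf, Dusp6, Spry4, Etv5, Egr1, Fos, Ccnd1, Kitl, Fgf2, Sox9, Amh and Gata4), and up to 4 members of each list that passed or, where none did, up to 2.

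The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median of probes well above background, no filter, a filter to probes well above background on all 6 arrays, the deposited table, the mean of a gene's detected probes, eBayes with trend and robust, a fit of the 4 arrays compared, the replicate number as a block, each array left out in turn, and a threshold of at least 2-fold. The files hold no mean spot signal, so normexp was run on the spot and background medians. Overlaps of the 2 comparisons with vehicle were set against 100 simulations of unchanged groups that shared the control arrays.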

Results

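Transcript levels were measured in cultures from C57BL/6J mice that the labels name primary Sertoli cells. Sertoli cells are the somatic cells of the seminiferous tubule that surround and nourish the germ cells. The cells had been cultured in medium with insulin, transferrin and epidermal growth factor (EGF) and were then treated for 24 h. The treatments were vehicle, basic fibroblast growth factor (bFGF, given in the labels as 20 ng with no volume) and 10 µM PD0325901, a small-molecule inhibitor of the kinases MEK1 and MEK2, which activate ERK. There were 2 samples in each of the 3 groups, each on its own 1-colour array. The array's 75th percentile signal lay between 1464 and 1613 on the 6 arrays. Well above background were 64.9% to 66.6% of the probes on the vehicle and PD0325901 arrays against 75.6% and 75.9% on the bFGF arrays. Of 16535 genes with a named probe, 14236 were well above background on both arrays of at least 1 group and were tested. Some markers of other cells were bright. Relative to the 75th percentile, the vehicle mean on the log2 scale was 4.57 for Acta2 (myoid) and 3.57 for Ldhc (germ cell). It was 3.49 for Dcn (fibroblast) and 3.17 for Lyz2 (macrophage), against 3.59 for the Sertoli cell gene Sox9. Others were dimmer, such as Ddx4 (germ cell, -0.52) and Emcn (endothelial, -3.21). These signals do not give shares of cells, so a change cannot be assigned to Sertoli cells alone. The labels do not say that the samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, with a median standard error (SE) of 0.07 on the log2 scale. Each group lay on a slide of its own, so slide and treatment cannot be told apart in any comparison. The bFGF arrays also lay at slide positions 3 and 4, and the arrays of the other groups at positions 1 and 2. The spread of the negative control spots was 7.50 and 8.31 on the bFGF arrays. It was 15.9 and 15.0 on the vehicle arrays and 11.1 and 12.7 on the PD0325901 arrays.

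The comparison of PD0325901 with vehicle asked which transcripts change when MEK is blocked in cells that receive EGF. Dusp6, the phosphatase that switches ERK off and is itself induced by ERK, fell by 6.07 ± 0.07 on the log2 scale (SE, n = 2 arrays per group, 67.2-fold). Egr2 and Egr1, immediate early transcription factors, fell by 5.85 ± 0.07 and by 3.77 ± 0.06. Etv5, a transcription factor that Sertoli cells need to maintain spermatogonial stem cells, was at least 18.4-fold lower, and Spry4, a feedback inhibitor of receptor signalling, at least 5.99-fold lower, both with signals not well above background under the inhibitor. Gdnf, the secreted factor that sustains spermatogonial stem cell self-renewal, fell by 2.46 ± 0.06 (5.52-fold, limma adjusted p = 9.35e-05).

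**Figure D1:**
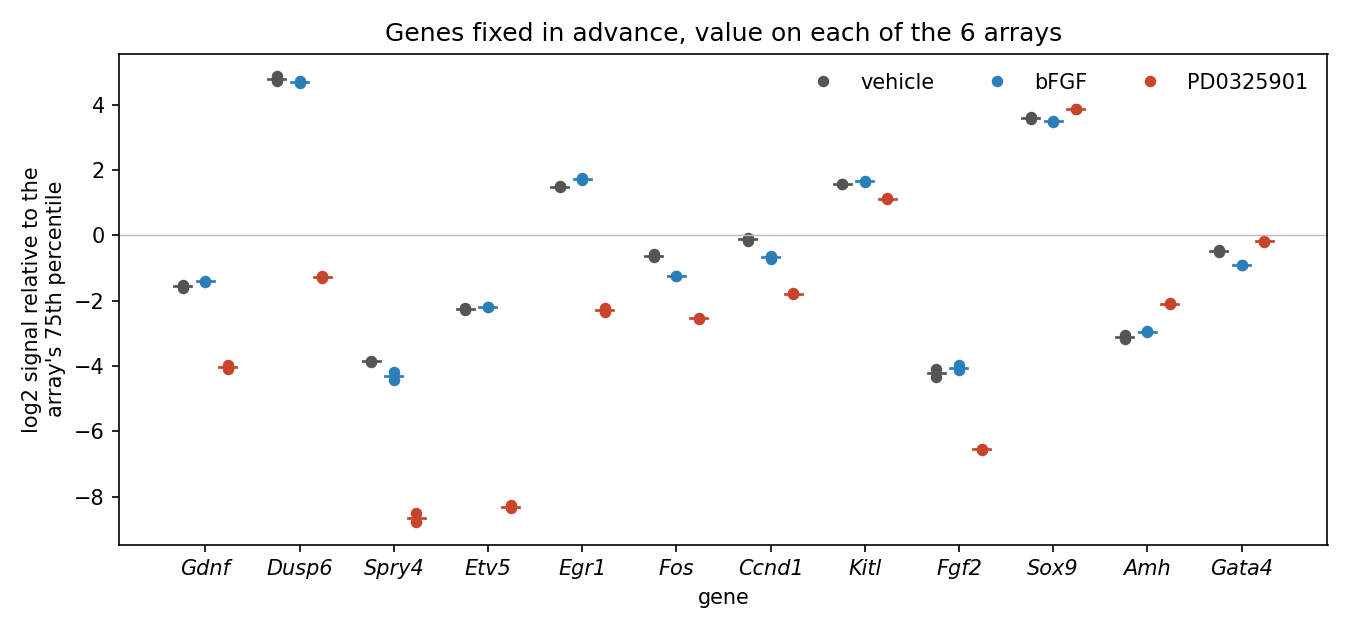
Values of 12 genes fixed in advance on each of the 6 arrays, as log2 signal relative to the array's 75th percentile (vertical axis), with 1 point per array, a line at the mean of the 2 arrays of a group, and colours for vehicle, bFGF and PD0325901. For Dusp6 the PD0325901 points lie near -1.28 and the vehicle and bFGF points near 4.79 and 4.68.

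In the list of ERK pathway outputs and feedback regulators, 24 of the 29 measured members fell, 3 rose and 2 did not pass the test. Over all 14236 tested genes 53.4% passed in this comparison, 3428 higher and 4168 lower, and the list counts below are to be read against that share. Besides those named above, Fos, an immediate early gene, fell by 1.92 ± 0.05, and Ccnd1, which encodes cyclin D1 of the G1 phase, fell by 1.66 ± 0.05. Higher under the inhibitor were Cdc42ep2 (1.58), Hbegf (0.42), Myc (0.40) and Il17rd (0.19), of which 3 passed. The list shifted down as a set (camera adjusted p = 1.26e-08, and adjusted p = 0.231 with an estimated correlation). Lower outside that list were Serpinb2, a plasminogen activator inhibitor (at least 57.0-fold), Klrb1a, a receptor of natural killer cells (at least 19.3-fold), Lce1g, a cornified envelope gene (at least 15.5-fold), Prkg2, a cGMP-dependent kinase (at least 11.9-fold), and Krt23, a keratin (at least 10.7-fold). The other detected probe of Lce1g fell by only 1.22 on the log2 scale, less than that bound. Has2, a hyaluronan synthase, fell by 5.17 ± 0.06, and Slco4a1, an organic anion transporter, by 4.95 ± 0.18, each well above background on 1 of the 2 PD0325901 arrays.

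Of 20 measured spermatogonial niche factors, 12 fell, 2 rose and 6 did not pass. Inhba, the activin and inhibin beta A subunit, fell by 1.75 ± 0.05, Cyp26b1, which degrades retinoic acid, by 1.97 ± 0.08, and Kitl, the ligand of the Kit receptor on spermatogonia, by 0.45 ± 0.04. The other detected probe of Kitl fell by 1.08. Fgf2, the gene of bFGF itself, was at least 4.57-fold lower. The largest positive differences in the list were those of Tgfb2 (1.09) and Wnt5a (1.05). The set shifted down (camera adjusted p = 0.00441, and adjusted p = 0.231 with an estimated correlation). Sertoli cell genes moved both ways: 10 of 29 rose, 9 fell and 10 did not pass, with no shift of the list against other genes (camera adjusted p = 0.598). Espn, an actin-bundling protein of Sertoli cell junctions, fell by 4.37 ± 0.09, whereas Fabp3, a fatty acid binding protein, rose by 2.85 ± 0.05, Gata1 by 1.91 ± 0.05, Ptgds, a prostaglandin D synthase, by 1.68 ± 0.04 and Amh, anti-Müllerian hormone, by 1.01 ± 0.06. The Sertoli cell transcription factors Sox9 and Gata4 rose by 0.28 ± 0.04 and 0.30 ± 0.04. Of 17 retinoid genes, 7 rose, 4 fell (5 adjusted over the list alone) and 6 did not pass (camera adjusted p = 0.420): Aldh1a3, which makes retinoic acid, fell by 3.69 ± 0.09, and the secreted retinol carrier Rbp4 rose by 1.40 ± 0.14.

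All 30 measured cell cycle genes fell (camera adjusted p = 2.88e-10, and adjusted p = 0.100 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell by 2.58 ± 0.04, and Cdc6, Ccne2 and Cdt1, which act at the start of DNA replication, fell by 1.99 ± 0.29, 1.99 ± 0.08 and 1.82 ± 0.06. Of 21 cholesterol synthesis genes, 20 fell and 1 did not pass (camera adjusted p = 9.41e-08, and adjusted p = 0.307 with an estimated correlation). Among them Insig1, a sterol sensor partner, fell by 1.35 ± 0.07, Stard4 by 1.29 ± 0.04 and the demethylase Cyp51 by 1.24 ± 0.05.

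Cytokine and acute inflammation genes fell in 12 of 19 cases, rose in 3 and did not pass in 4 (camera adjusted p = 0.0107, and adjusted p = 0.231 with an estimated correlation). Il11 fell by 3.52 ± 0.07, the prostaglandin synthase gene Ptgs2 by 3.01 ± 0.14 and Il6 by 2.60 ± 0.15. Macrophage markers moved in the same direction on these arrays, where 6 of 13 fell (4 adjusted over the list alone) and 7 did not pass (camera adjusted p = 0.0401, and adjusted p = 0.637 with an estimated correlation). The complement gene C1qa fell by 1.54 ± 0.20 and the lysozyme gene Lyz2 by 0.72 ± 0.09. Of 10 endothelial markers, 4 fell and 6 did not pass (camera adjusted p = 0.0567). Among those that fell were Emcn, by 2.34 ± 0.15, and the VEGF receptor gene Flt1, by 2.28 ± 0.09. A smaller share of the macrophage and endothelial lists passed than of all tested genes (53.4%), although every member that passed fell. The macrophage shift did not pass without vehicle replicate 1 (adjusted p = 0.0658) or PD0325901 replicate 2 (0.0676), and the endothelial list passed without vehicle replicate 1 (0.0299), vehicle replicate 2 (0.0325) or PD0325901 replicate 1 (0.0192). Interferon response genes rose in 18 of 26 cases and did not pass in 8 (camera adjusted p = 1.87e-06, and adjusted p = 0.416 with an estimated correlation). Usp18, which restrains interferon signalling, rose by 2.04 ± 0.16, the antiviral gene Rsad2 by 1.96 ± 0.34 and the transcription factor gene Irf7 by 1.33 ± 0.16. Of 20 stress response and apoptosis genes, 11 rose, 4 fell and 5 did not pass (camera adjusted p = 0.0117, and adjusted p = 0.231 with an estimated correlation). The heat shock protein genes Hspa1a and Hspa1b, which are close copies of each other and may share signal, rose by 2.67 ± 0.04 and 2.64 ± 0.04, and Atf3, a stress-induced transcription factor, by 1.87 ± 0.04.

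Abra, an actin-binding protein gene of striated muscle, was at least 9.16-fold higher, Myl1 and Actn3, components of the striated muscle sarcomere, rose by 3.96 ± 0.11 and 3.85 ± 0.07, and Pdlim3, which binds alpha-actinin, rose by 3.74 ± 0.14. Omd and Aspn, small proteoglycans of matrix, were at least 3.56-fold and 4.18-fold higher, the keratin gene Krt20 at least 12.2-fold and Clca1 at least 4.68-fold, and Btnl10, a butyrophilin family member, rose by 4.43 ± 0.12. Of 9 peritubular myoid and smooth muscle markers, 6 rose and 3 did not pass (camera adjusted p = 0.00260, and adjusted p = 0.571 with an estimated correlation): Des, which encodes desmin, rose by 2.86 ± 0.09, the calponin gene Cnn1 by 2.48 ± 0.11, Acta2 by 0.79 ± 0.08 and Lmod1 by 0.73 ± 0.09. Of 11 fibroblast and stromal markers, 6 rose, 1 fell (2 adjusted over the list alone) and 4 did not pass (camera adjusted p = 0.0878). Mfap5 rose by 1.89 ± 0.15 and Postn, which encodes periostin, by 1.63 ± 0.04.

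The other lists did not shift against the other genes in camera. In fry, which asks only whether a list moves one way, several passed. Downward were proteases (fry adjusted p = 4.31e-04), extracellular matrix (0.00627), endothelial (0.00680) and Leydig cell (0.0453) lists. Upward were the Sertoli cell (0.00203), fibroblast (0.00251) and rete (0.0415) lists. The junction, glycolysis, receptor, FSH and cAMP, germ cell and retinoid lists did not pass in fry. Matrix proteases and their inhibitors rose in 5 cases of 21 (6 adjusted over the list alone) and fell in 11 (camera adjusted p = 0.134), and the stromelysin genes Mmp3 and Mmp10 fell by 3.27 ± 0.18 and 2.42 ± 0.05. Of 23 extracellular matrix genes, 6 rose (7 adjusted over the list alone) and 9 fell (camera adjusted p = 0.812), among them the tenascin gene Tnc, by 3.09 ± 0.09, and the osteopontin gene Spp1, by 2.53 ± 0.05. Of 21 junction genes, 7 rose and 7 fell (8 adjusted over the list alone, camera adjusted p = 0.611). Glycolysis and lactate genes rose in 7 and fell in 8 of 22 cases (camera adjusted p = 0.812). Growth factor receptors rose in 5 (6 adjusted over the list alone) and fell in 9 of 20 cases (camera adjusted p = 0.812). Kit rose by 1.76 ± 0.10 and the VEGF receptor gene Kdr fell by 1.49 ± 0.11. FSH and cAMP genes rose in 9 and fell in 4 of 16 cases (camera adjusted p = 0.231). The orphan nuclear receptor gene Nr0b1 rose by 2.06 ± 0.27 and Nr5a2 fell by 1.46 ± 0.19. Leydig cell markers rose in 1 and fell in 3 of 8 cases (camera adjusted p = 0.426). Germ cell markers rose in 3 (2 adjusted over the list alone) and fell in 3 of 16 (camera adjusted p = 0.598), and rete and epithelial markers rose in 2 and fell in 1 (0 adjusted over the list alone) of 8 (camera adjusted p = 0.391). Where no other count is given, the same numbers passed when adjusted over the list alone. The mean and the median change differed in sign in the Sertoli cell, retinoid, extracellular matrix, glycolysis and germ cell lists, none of which shifted in camera.

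In all, 7596 of 14236 genes passed the threshold between PD0325901 and vehicle (limma, Benjamini-Hochberg), 3428 higher and 4168 lower, and with quantile normalization 3844 higher and 3463 lower, so which direction held more genes depends on the scaling. A change of at least 2-fold was found for 579 higher and 1094 lower genes, of which 116 and 445 were not well above background on at least 1 array of the 2 groups. None of the 9 lists that shifted with the preset correlation did so with an estimated one, a form that rests on 3 residual degrees of freedom. In the cell cycle, niche, cytokine and stress lists the estimate lay under the preset 0.01 (-0.0185, -0.0083, -0.0264 and -0.0348). A larger correlation is thus not why these lists no longer passed. In the other lists that shifted it was larger, from 0.0899 to 0.497. The slide of the PD0325901 arrays held no vehicle array.

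The comparison of bFGF with vehicle asked which transcripts respond to the growth factor in the same medium. Fos fell by 0.62 ± 0.05 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 0.00846), Ccnd1 by 0.55 ± 0.05 and Gata4 by 0.43 ± 0.04. The EGF receptor ligand genes Ereg and Areg rose by 0.85 ± 0.17 and 0.75 ± 0.12, and Fosl1, an AP-1 transcription factor, by 0.72 ± 0.06. None of these genes passed without bFGF replicate 2, where limma called 0 genes (3722 at an unadjusted p under 0.05). Gdnf differed by 0.15 ± 0.06, which did not pass the test (limma adjusted p = 0.158). Neither did Dusp6 (-0.11 ± 0.07, adjusted p = 0.320), Etv5 (0.06 ± 0.05), Spry4 (-0.46 ± 0.13), Egr1 (0.23 ± 0.06), Kitl (0.08 ± 0.04), Fgf2 (0.16 ± 0.10), Amh (0.16 ± 0.06) or Sox9, which differed by -0.11 ± 0.04, with 2 of its 3 detected probes of that sign.

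Of the 29 ERK pathway genes, 6 rose (7 adjusted over the list alone), 4 fell and 19 did not pass (camera adjusted p = 0.839). Over all tested genes 19.9% passed in this comparison. Of 20 niche factors, 2 rose, 2 fell and 16 did not pass (camera adjusted p = 0.767). Tgfb2 fell by 0.83 ± 0.06, Cyp26b1 rose by 0.44 ± 0.08 and Wnt6 rose by 0.31 ± 0.05. Sertoli cell genes rose in 7 (8 adjusted over the list alone) and fell in 2 of 29 cases (camera adjusted p = 0.725): Gata1 rose by 0.76 ± 0.05, the X-linked testis gene Tsx by 0.74 ± 0.13 and Espn by 0.58 ± 0.09, and the keratin gene Krt18 fell by 0.55 ± 0.08. Retinoid genes rose in 4 and fell in 2 (3 adjusted over the list alone) of 17 cases (camera adjusted p = 0.767). The reductase and dehydrogenase genes Dhrs3 and Rdh10 rose by 0.56 ± 0.07 and 0.42 ± 0.06.

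Cytokine and acute inflammation genes rose in 11 of 19 cases (13 adjusted over the list alone), and 8 did not pass (camera adjusted p = 2.92e-04, and adjusted p = 0.434 with an estimated correlation). Ccl2, a monocyte chemoattractant, rose by 0.99 ± 0.05, and the neutrophil chemokine gene Cxcl5 and the Tnf gene, not well above background on the vehicle arrays, were at least 1.92-fold and 1.81-fold higher. Interferon response genes rose in 10, fell in 1 and did not pass in 15 of 26 cases (camera adjusted p = 0.00299, and adjusted p = 0.902 with an estimated correlation). Gbp3 rose by 0.79 ± 0.13 and Oasl2 by 0.68 ± 0.08. Cholesterol synthesis genes fell in 12 of 21 cases (16 adjusted over the list alone), and 9 did not pass (camera adjusted p = 4.16e-08, and adjusted p = 0.542 with an estimated correlation). Fdps fell by 0.49 ± 0.06, Dhcr7 by 0.40 ± 0.06 and Lss by 0.37 ± 0.05, all enzymes of the pathway. Of 30 cell cycle genes, 5 fell and 25 did not pass (camera adjusted p = 0.00973, and adjusted p = 0.442 with an estimated correlation). That list did not pass with quantile normalization (adjusted p = 0.0974) or with probes above background on all 6 arrays (adjusted p = 0.0504). The mitotic cyclin gene Ccnb2 fell by 0.40 ± 0.05 and E2f1 by 0.30 ± 0.06. Germ cell markers rose in 7 of 16 cases (13 adjusted over the list alone), and 9 did not pass (camera adjusted p = 0.00299, and adjusted p = 0.902 with an estimated correlation). Stra8, a meiotic entry gene, rose by 1.02 ± 0.17, Ldhc by 0.69 ± 0.14 and the germ cell helicase gene Ddx4 by 0.50 ± 0.08.

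**Figure D2:**
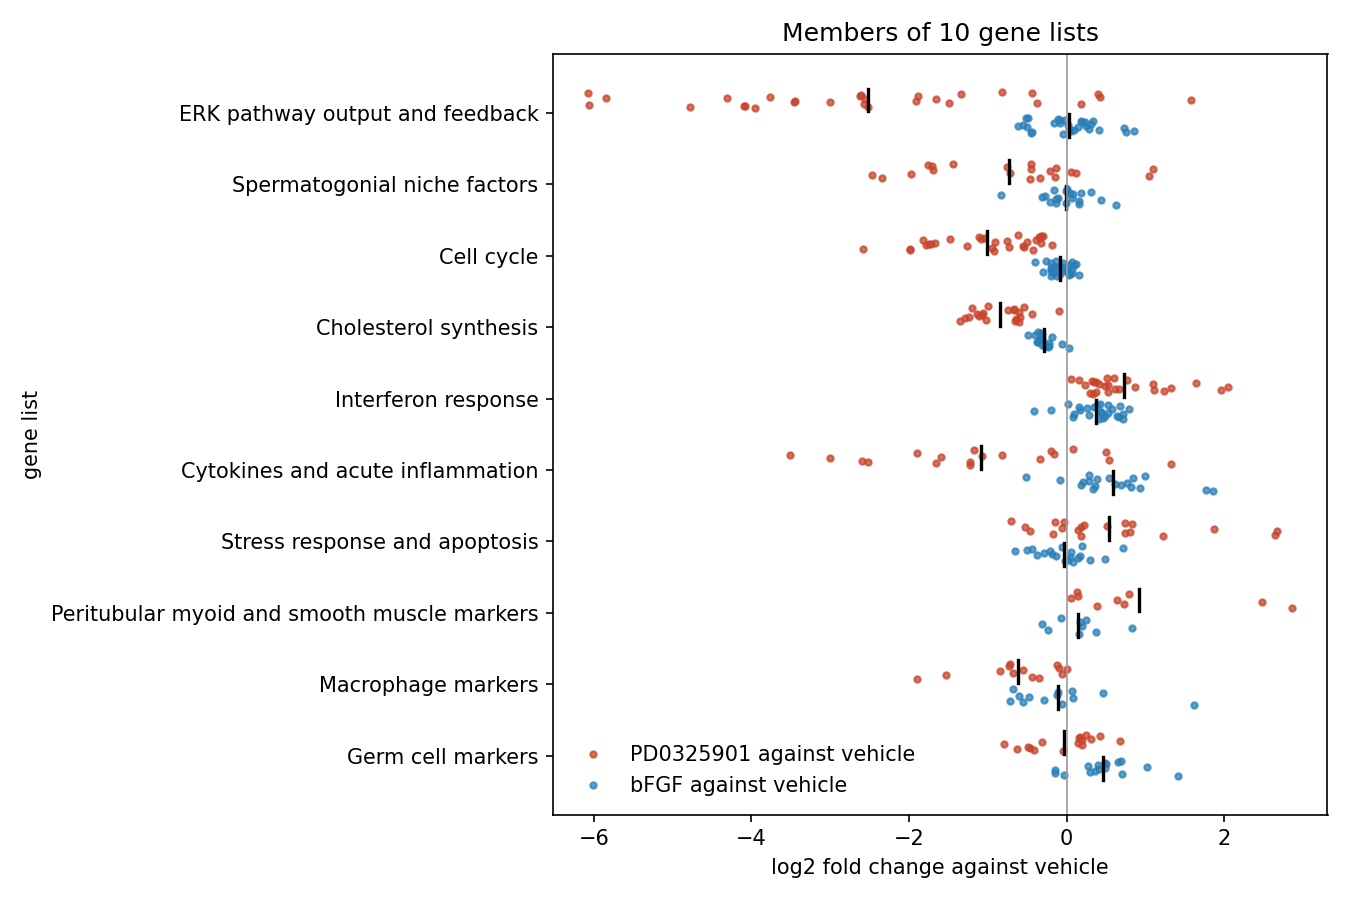
Fold change against vehicle, on the log2 scale (horizontal axis), of each measured member of the 10 gene lists that shifted in either comparison with vehicle, with 1 point per gene, a black line at the list's mean, and colours for PD0325901 and bFGF. The mean of the ERK pathway list lies at -2.52 under PD0325901 and at 0.03 under bFGF.

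Among the largest falls were those of Grem1, an antagonist of bone morphogenetic proteins, by 2.09 ± 0.10, the beta-tubulin gene Tubb2b, by 2.01 ± 0.11 and Irs1, an insulin receptor substrate, by 1.70 ± 0.18. Col24a1, a collagen gene, was at least 2.26-fold lower, although without a filter another probe stands for it, which differed by 1.20 in the other direction. Ranked by signal alone, the first 10 rises were in genes not well above background on the vehicle arrays, and their bounds, from at least 1.33-fold to at least 3.13-fold, do not place them above rises that were measured. They were 7 olfactory receptor genes, which encode odorant receptors of the nose, 2 vomeronasal receptor genes (Vmn1r172 and V1rd19) and the nicotinic receptor subunit gene Chrna2. Among the olfactory receptor genes, Olfr435 was at least 3.13-fold higher and Olfr1181 at least 1.92-fold. In the FSH and cAMP list, 4 genes rose (8 adjusted over the list alone) and 1 of 16 fell (camera adjusted p = 0.0942), with Nr0b1 rising by 1.87 ± 0.27.

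The other lists did not shift against the other genes in camera. The protease list depended on single arrays: its mean was -0.17 without bFGF replicate 2, against -0.13 with all arrays. Stress response genes rose in 3 (4 adjusted over the list alone) and fell in 7 of 20 cases (camera adjusted p = 0.570), with the heme oxygenase gene Hmox1 rising by 0.71 ± 0.04. Matrix proteases and inhibitors rose in 2 and fell in 4 of 21 cases (4 and 8 adjusted over the list alone, camera adjusted p = 0.0942), among them Adamts5, an aggrecanase, which fell by 1.34 ± 0.15. Extracellular matrix genes rose in 1 and fell in 6 of 23 cases (2 and 7 adjusted over the list alone, camera adjusted p = 0.282), with the elastin gene Eln rising by 1.08 ± 0.14. Junction genes rose in 3 and fell in 2 of 21 cases (camera adjusted p = 0.989). Glycolysis genes rose in 3 and fell in 0 of 22 (5 and 1 adjusted over the list alone, camera adjusted p = 0.849), and growth factor receptors rose in 2 and fell in 1 of 20 (camera adjusted p = 0.864), with Egfr rising by 0.45 ± 0.06. Of the markers of other cell types, myoid markers rose in 1 and fell in 1 of 9 cases (camera adjusted p = 0.731) and Leydig cell markers fell in 1 of 8 (camera adjusted p = 0.808). Macrophage markers rose in 1 and fell in 1 of 13 (camera adjusted p = 0.282), fibroblast markers fell in 2 of 11 (camera adjusted p = 0.570) and rete markers rose in 2 (3 adjusted over the list alone) and fell in 1 of 8 (camera adjusted p = 0.856). No endothelial marker passed among 10 (limma, 0 also adjusted over the list alone, camera adjusted p = 0.767). One of them, Tie1, differed by -2.69 ± 1.65 because its 2 vehicle arrays had an SD of 3.39. The mean differed in sign from the median or from the test in the ERK, Leydig cell, fibroblast and rete lists.

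In all, 2834 of 14236 genes passed between bFGF and vehicle (limma, Benjamini-Hochberg), 1797 higher and 1037 lower. Without a filter they were 1873 and 1644, with trend and robust eBayes 2360 and 1765, and with probes above background on all 6 arrays 1574 and 1284. At least 2-fold, 504 were higher and 34 lower. Of the 504, 379 were not well above background on at least 1 array of the 2 groups, and 346 of them on neither array of at least 1 group. The count depended on single arrays: without bFGF replicate 2 limma called 0 genes (3722 at an unadjusted p under 0.05), without replicate 1 of bFGF 545, without replicate 1 or 2 of vehicle 1882 and 1789, and without either PD0325901 array, which only adds to the estimate of the spread, 1139. None of the 5 lists that shifted did so with an estimated correlation, a form that rests on 3 residual degrees of freedom.

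Genes moved by both treatments were compared gene by gene. Serpinb2, Espn, Cyp26b1 and the connexin gene Gjb2 rose under bFGF and fell under PD0325901, by 0.73 ± 0.12 and -1.10 ± 0.12 for Gjb2. Gata4 and the ciliogenesis transcription factor gene Foxj1 fell under bFGF and rose under PD0325901, Foxj1 by -0.68 ± 0.07 and 1.36 ± 0.07. Gata1, Nr0b1, Gbp3 and Cnn1 rose under both, and Fos, Ccnd1, Spp1 and Lyz2 fell under both. Over all tested genes, 604 rose under bFGF and fell under PD0325901, and 368 fell under bFGF and rose under PD0325901. Another 519 rose and 401 fell under both. Independent lists of these sizes would share 526, 250, 433 and 304 genes, and unchanged groups simulated against the same controls shared 0 of each. That 0 leaves out real effects, so it does not show what shared controls add among changed genes. Across genes, which are not independent replicates, the fold changes had a Pearson r of -0.042 and a covariance of -0.0147, against 0.499 and 0.0175 in the simulation, a difference in covariance of -0.0322. The simulated r is what shared controls give in unchanged groups, so it is no reference for groups with changed genes. Among the 12332 genes well above background on all 6 arrays the r was 0.030 and the covariance 0.00562, so the negative sign was not seen in them. The 4 overlaps among these genes were 367, 364, 456 and 386 genes against 353, 269, 325 and 292 for independent lists. Part of the excess of genes moved the same way may come from the shared controls, which were not split because each part would hold 1 array. Both comparisons also use 1 estimate of each gene's spread, so genes with a small spread can pass in both more often than independent lists allow. That can raise all 4 overlaps, so the excess of genes moved in opposite directions is not shown to be an opposition of the treatments. These counts depended on single arrays. Raised by bFGF and lowered by PD0325901 were 0 genes without bFGF replicate 2 (limma, 3722 at an unadjusted p under 0.05 for bFGF), 130 without bFGF replicate 1, and 307 and 295 without PD0325901 replicates 1 and 2. The reverse were 0 without bFGF replicate 2, 46 without bFGF replicate 1, 188 and 172 without vehicle replicates 1 and 2, and 96 and 101 without PD0325901 replicates 1 and 2. The r was 0.020 and 0.099 without vehicle replicates 1 and 2.

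The direct comparison of bFGF with PD0325901 set the 2 treatments against each other. It is the bFGF change minus the PD0325901 change, so it does not tell which treatment moved a gene. Against vehicle, the mean changes under bFGF and PD0325901 were both negative for cholesterol synthesis (-0.29 and -0.84) and cell cycle genes (-0.08 and -1.01). For interferon genes both were positive (0.37 and 0.73), and for cytokine genes they were opposite (0.59 and -1.08). Serpinb2 was at least 102-fold higher under bFGF, Egr2 was higher by 6.15 ± 0.07 on the log2 scale (SE, n = 2 arrays per group), Dusp6 by 5.96 ± 0.07 and Egr1 by 4.00 ± 0.06, and Etv5 was at least 19.1-fold higher. Gdnf was higher by 2.61 ± 0.06 (6.13-fold, limma adjusted p = 8.38e-05), Cyp26b1 by 2.41 ± 0.08, the Wnt ligand gene Wnt6 by 2.02 ± 0.05 and the FSH receptor gene Fshr by 1.42 ± 0.05. Map7d3, a microtubule-associated protein gene, and Ubash3b, a phosphatase gene, were both higher by 5.04, with SEs of 0.04 and 0.06. Lower under bFGF were Abra (at least 16.3-fold), Csrp3, a muscle LIM protein gene (at least 4.26-fold), Pdlim3 by -3.67 ± 0.14, Actn3 by -3.65 ± 0.07, Fibin, a secreted protein gene, by -3.65 ± 0.07 and Klhl30, a kelch family gene of muscle, by -3.62 ± 0.12.

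ERK pathway genes were higher under bFGF in 24 of 29 cases, lower in 3 and did not pass in 2 (camera adjusted p = 1.19e-06, and adjusted p = 0.259 with an estimated correlation). Ereg was at least 10.7-fold higher. Over all tested genes 62.0% passed in this comparison, 5205 higher and 3622 lower under bFGF. Niche factors were higher in 13 of 20 cases and lower in 2 (camera adjusted p = 0.0328, and adjusted p = 0.313 with an estimated correlation). Cell cycle genes were higher in 25 of 30 cases and lower in 0 (camera adjusted p = 1.19e-06, and adjusted p = 0.201 with an estimated correlation). The thymidine kinase gene Tk1 was higher by 1.81 ± 0.05. Cholesterol synthesis genes were higher in 18 of 21 cases (19 adjusted over the list alone) and lower in 0 (camera adjusted p = 3.03e-04, and adjusted p = 0.598 with an estimated correlation). Cytokine genes were higher in 16 of 19 and lower in 1 (camera adjusted p = 3.03e-04, and adjusted p = 0.242 with an estimated correlation). Il11 was higher by 3.80 ± 0.07 and Ptgs2 by 3.62 ± 0.14. Interferon genes were higher in 2 and lower in 11 of 26 cases (camera adjusted p = 0.00438, and adjusted p = 0.692 with an estimated correlation). Stress genes were higher in 4 and lower in 11 of 20 (13 lower adjusted over the list alone, camera adjusted p = 0.00438, and adjusted p = 0.259 with an estimated correlation), and myoid markers lower in 6 of 9 (camera adjusted p = 0.00530, and adjusted p = 0.692 with an estimated correlation). Macrophage markers were higher in 6 of 13 cases (camera adjusted p = 0.384), endothelial markers in 5 of 10 (camera adjusted p = 0.0712) and germ cell markers in 9 of 16 (camera adjusted p = 0.0524). Of 11 fibroblast markers 6 were lower and 1 higher (2 higher adjusted over the list alone, camera adjusted p = 0.0524). The niche shift did not pass without bFGF replicate 2 (adjusted p = 0.0513). The germ cell list passed without either vehicle replicate (0.0392 each) or bFGF replicate 1 (0.0168), the endothelial list without either vehicle replicate (0.0392 each) or PD0325901 replicate 1 (0.0345), and the fibroblast list without bFGF replicate 2 (0.0175) or PD0325901 replicate 2 (0.0397).

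The remaining lists did not shift against the other genes between bFGF and PD0325901 in camera. Sertoli cell genes were higher in 10 and lower in 10 of 29 cases (camera adjusted p = 0.447), retinoid genes in 6 and 9 of 17 (camera adjusted p = 0.447), with Aldh1a3 higher by 3.65 ± 0.09, and junction genes in 9 and 7 of 21 (8 lower adjusted over the list alone, camera adjusted p = 0.802). Proteases and inhibitors were higher in 11 and lower in 6 of 21 cases (camera adjusted p = 0.497), with Adamts5 lower by -3.57 ± 0.15. Matrix genes were higher in 9 and lower in 5 of 23 (camera adjusted p = 0.855), with Tnc higher by 2.77 ± 0.09, and glycolysis genes in 9 and 6 of 22 (10 and 7 adjusted over the list alone, camera adjusted p = 0.843). Growth factor receptors were higher in 9 (10 adjusted over the list alone) and lower in 7 of 20 cases (camera adjusted p = 0.859), FSH and cAMP genes in 6 and 6 of 16 (camera adjusted p = 0.820), Leydig cell markers in 4 and 2 of 8 (camera adjusted p = 0.802) and rete markers in 2 and 2 of 8 (camera adjusted p = 0.820). The mean differed in sign from the median or from the test in the Sertoli cell, retinoid, glycolysis, FSH and cAMP, and rete lists. In all, 8827 of 14236 genes passed (limma, Benjamini-Hochberg), 5205 higher and 3622 lower under bFGF, of which 2145 and 531 by at least 2-fold. Of these, 1116 and 30 were not well above background on at least 1 array of the 2 groups. The split was 4299 higher and 3957 lower with quantile normalization, and 4156 and 3683 with probes above background on all 6 arrays. These 2 groups also lay on separate slides.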

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

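The inclusion of transcripts without a gene symbol and the common floor on dim signals were chosen after seeing the data. The 3 counts of changed genes stayed within 1.5 times of 7596, 2834 and 8827 under normexp, quantile normalization, median scaling, both filters, the deposited table, probe means, trend and robust eBayes, and the common floor. With transcripts without a symbol, which enlarge the set tested, 13453 differed between bFGF and PD0325901. At least 2-fold, 1673, 538 and 2676 genes passed, and 82 were raised by bFGF and lowered by PD0325901 and 9 the reverse. With only the 4 arrays compared, which leaves fewer residual degrees of freedom, 1139 genes passed between bFGF and vehicle. The samples share only a replicate number: deviations of same-numbered arrays correlated at -0.077 between vehicle and bFGF, 0.120 between vehicle and PD0325901 and -0.117 between bFGF and PD0325901. With the number as a replicate block 6955, 1410 and 8183 genes passed, and 332 and 176 moved in opposite directions, with fewer residual degrees of freedom. Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 5084 to 7198 genes for PD0325901, 0 to 1882 for bFGF (0 without bFGF replicate 2 in limma, with 3722 at an unadjusted p under 0.05, and 545 without its replicate 1) and 6305 to 9228 for bFGF against PD0325901. It gave 0 to 466 genes raised by bFGF and lowered by PD0325901, and 0 to 188 of the reverse. Genes raised by bFGF and lowered by PD0325901 were 354 with quantile normalization, and genes of the reverse were 559 with trend and robust eBayes. The cause was not tested. The r of the fold changes turned from -0.042 to 0.072 with normexp, 0.058 with quantile normalization, 0.073 without a filter, 0.029 with probes above background on all 6 arrays and 0.029 with the floor, and lay between -0.052 and 0.099 with 1 array left out. The cause was not tested. Of the lists, 8 to 10 shifted under PD0325901 with 1 array left out, 5 or 6 under bFGF and 8 to 10 between them. Under the other scalings, filters and values 9 or 10, 4 or 5 and 8 to 10 did. The cell cycle list under bFGF was lost with quantile normalization and with probes above background on all 6 arrays. Endothelial markers under PD0325901 newly passed with quantile normalization (adjusted p = 0.0479) and median scaling (adjusted p = 0.0482). Between bFGF and PD0325901, fibroblast markers newly passed with normexp and the deposited table, and germ cell and endothelial markers without a filter and with probes above background on all 6 arrays. With an estimated correlation, which rests on 3 residual degrees of freedom, the counts were 0, 0 and 0 in camera, with smallest adjusted p of 0.100, 0.434 and 0.201. In fry, which asks only whether a list moves one way, they were 16, 5 and 16. Under bFGF these were not the same 5 lists as in camera. The interferon and germ cell lists did not pass (fry adjusted p = 0.0514 each), and the Sertoli cell (0.0279) and FSH and cAMP (0.0191) lists did. Of the values of named genes under an alternative, 5113 kept their direction or their side of the threshold, 8 newly passed and 595 no longer passed. Reversed were Col24a1 under bFGF without a filter, at 1.20 (adjusted p = 0.0113), where another probe stands for the gene, and Pax2 between bFGF and PD0325901 with quantile normalization, at -0.16 (adjusted p = 0.318), for which the cause was not tested. A slide block could not be fitted because each slide held 1 group. Signal over background limits what was measured for dim genes, since the bFGF arrays detected 75.7% of probes on average and the vehicle and PD0325901 arrays 66.3% and 65.7%.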

Other observations

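The spike-in test, the olfactory receptor test, the common floor, the myoid marker test and the striated muscle test were chosen, or given their present form, only after the results they bear on had been seen. Other genes of the contractile apparatus moved with PD0325901 in both directions. In a list of striated muscle genes, without 6 of those already seen, 16 of 39 measured members rose, 8 fell (9 adjusted over the list alone) and 15 did not pass the test. Among genes singled out from that list after their values were seen, Mybpc3, a cardiac myosin binding protein gene, rose by 2.10 ± 0.10 on the log2 scale, the cardiac troponin gene Tnni3 by 2.40 ± 0.08 and the M-band gene Myom2 by 2.22 ± 0.12. Myoz1, a calcineurin-binding sarcomere gene, fell by 2.32 ± 0.08 and the slow troponin gene Tnni1 by 1.10 ± 0.07.

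A first hypothesis was that these rises belong to a striated muscle program. The list did not pass (camera p = 0.0980 with the preset correlation, and p = 0.147 with an estimated correlation), but it leaves out genes already seen and its members went both ways, so the hypothesis stays open. Under bFGF 7 of the 39 genes rose and 2 fell, with a mean of 0.34 against 0.28 under PD0325901, and camera gave p = 0.118 with the preset correlation, so the mean was no larger with the inhibitor. Some of the 39 genes were dim, and other dim genes also tended to be higher on the bFGF arrays (median 0.21). The 2 means therefore do not decide the hypothesis. Another 3 members, Myl2, Myh1 and Myh2, were first set aside as already seen and then put back before the test ran, although at least the fall of Myh1 had been seen. Without these 3 the p was 0.117 over 36 genes (0.166 with an estimated correlation).

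A second explanation of the same rises, that the PD0325901 cultures held more peritubular myoid cells, depends on the form of its test. The test first asked whether the abundant markers rise as much as the others, and in that form 3 of 6 abundant markers stayed under the median rise by over 2 SE, which by the bound set then counted against more myoid cells. After the changes of Actg2 (0.06 ± 0.05, the lowest of the 9 markers at 0.059), Tagln (0.13 ± 0.08) and Mylk (0.15 ± 0.06) had been seen, it was changed to the markers with low vehicle signals, since a high signal could hide a small number of added cells. In the changed form Des rose by 2.86 ± 0.09, Lmod1 by 0.73 ± 0.09 and Myh11 by 0.38 ± 0.10, which left the matter open, and because the change was made with values in view it carries little weight.

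A second pattern was the rise of dim genes under bFGF, where 346 of the 504 genes at least 2-fold higher were dim in 1 of the 2 groups and 118 of the 346 encode olfactory or vomeronasal receptors. Background subtraction by the extraction software is argued against as the only source. In the raw spot medians, set against the negative control spots of the same array, 100% of the 346 genes were higher under bFGF. Their median raw signal over those controls was 13.14 under vehicle and 27.25 under bFGF. The 346 genes were chosen by the processed signal of the same spots, so the 100% is not independent and a smaller part is not excluded. Deeper detection on the bFGF arrays stayed open: with 1 floor for all arrays 251 genes were at least 2-fold higher, 49.8% of 504, which barely meets the bound of under 50%, and 207 of them were among the 504. A floor lowers the fold of a dim gene whether its rise is real or not, so this count cannot separate the 2. A raised signal of dim probes in general stayed open, as 65.0% of 1003 olfactory and vomeronasal receptor genes were higher under bFGF than vehicle, and 10.5% of them under PD0325901 than vehicle (median -0.34), against 56.4% of 2665 other genes dim on both PD0325901 arrays higher under bFGF and 49.4% of genes well above background on all 6 arrays. The bounds of the olfactory receptor, background and floor tests were reworded before those tests ran, for the floor after its count of all called genes had been seen, and a response to bFGF was not tested apart from the slide.

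The third pattern was the number of genes called although each group lay on a slide of its own. Among 2579 genes called between PD0325901 and vehicle with another detected probe, the next brightest probe, at a median distance of 160 rows on the array, had the same sign in 92.4%, as it did in 89.2% of 765 genes called between bFGF and vehicle (81.4% and 70.7% over all genes, called or not), so artefacts of single probes or positions are argued against. The 7 spike-in probes well above background on all 6 arrays differed from vehicle, on signals not scaled by array, by at most 0.140 under PD0325901 and 0.178 under bFGF (0.073 and 0.109 in the scaled signals, on which this test was first run). That is less than the median absolute changes of 0.52 and 0.47 of the called genes, so these bright probes showed no slide difference of that size. The test decides little about the calls, since the scaling removes a shift of all signals before genes are called. It also cannot speak of dim probes, because only spike-in probes well above background were used. Because 0 slides held more than 1 group, a difference in culture, labelling or hybridisation that follows the slide cannot be told apart from the treatment.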
